A study of Mus musculus with 30 samples.

How the data were processed

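Lungs of mice given intratracheal bleomycin or saline were dissociated, sorted by flow cytometry and profiled by droplet-based 3' single-cell RNA sequencing, per the labels. The 30 samples formed 15 pairs of a gene expression library and a hashtag library, 1 pair for each of 5 treatments and 3 sort gates. Cells in every library had been stained with 5 hashtag antibodies, whose barcodes mark the set of cells each tag was mixed with. The labels do not say what 1 hashtag stands for, and name both a column-based RNA isolation and the droplet kit in the same protocol. All sets of a treatment and gate shared 1 library, so treatment and library cannot be told apart. No p-value measures the spread between libraries, and those of gene lists rest on spread over genes.

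The deposited values were raw UMI counts per gene and per hashtag for each called cell barcode, with no normalization, per the file headers and the values. Reads were aligned to GRCm38 and counted with Cell Ranger 6.0.1, and bcl2fastq was named without a version, per the submitters' processing notes. The annotation release was not given in the sources used here. GENCODE M21 on GRCm38 was used for coordinates, and 52403 of the 52636 gene identifiers in the deposited feature lists were found in it. Reads of genes with near-identical copies (Rpl39-ps, Ftl1-ps1, Rps27rt) can be split between copies by the authors' counting, so their values are uncertain.

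Barcodes with at least 300 genes and at most 15% mitochondrial UMIs were kept. A cell was assigned to a hashtag when its highest tag had at least 10 counts and at least 3 times the counts of the second. Cells with several tags were removed. The automatic Scrublet threshold marked between 0.0073% and 22.3% of cells of a library, so it was replaced: the number of doublets within a tag was computed from the cells with several tags, and that many single-tag cells with the highest Scrublet scores (expected rate 0.1) were removed. Each gate was clustered over its 5 libraries (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, seed 1; scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Clusters were named from marker lists fixed in advance. A marker counted when detected in at least 10% of a cluster's cells and at least 1 log2 unit above the other clusters (pseudocount 10 CPM), and 3 markers were needed. Clusters whose leading genes belonged to another class stayed unnamed, and clusters with over 40% called doublets were left out. These thresholds for naming and the number of doublets were set after the data were seen. All class names are rebuilt from these data, since no cell annotation was used, and each should be read as "like" that class.

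Counts were summed per class and hashtag set, for sets with at least 20 cells of the class, into 5 classes: fibroblasts (triple-negative gate), alveolar type 2 cells and general capillary endothelial cells (gate written CD31/EpCAM), and alveolar and interstitial macrophages (CD45+ gate). These were tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3; TMM normalization, filterByExpr, robust), with all 5 treatments of a class in 1 fit and Benjamini-Hochberg adjustment within each contrast, and an adjusted p below 0.05 counted as called. The 5 contrasts were bleomycin with isotype against PBS, each antibody and both antibodies against isotype, and the interaction, the change with both antibodies minus the sum of the changes with each. The isotype libraries served as control in 4 of these contrasts, which share their chance values. Fold changes are log2 with standard errors, and levels are in CPM.

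The 17 gene lists fixed before the data were examined were tested with limma 3.58.1 camera with a preset correlation of 0.01, adjusted over all lists, classes and contrasts, and again with an estimated correlation. They cover the response to gp130-STAT3 signalling, extracellular matrix, fibrotic fibroblasts, alveolar fibroblasts, the response to TGF-beta, transitional epithelium, surfactant and alveolar type 2 identity, acute-phase type 2 genes, MHC class II, the responses to interferon and to p53, scar-associated macrophages, alveolar macrophages, activated endothelium, cholesterol synthesis, the cell cycle and dissociation stress. Lists of clock genes of both phases and of mitochondrial ribosomal and messenger RNAs were added after the data were seen. The genes eligible for naming were the 3 with the largest rise and the 3 with the largest fall per class and contrast among called genes with non-overlapping sets (no such condition for the interaction) and at least 50 CPM in the higher group, up to 4 called members of each called list, and always Il6, Il6ra, Il6st, Osm, Osmr, Socs3 and Col1a1. Predicted, mitochondrial, haemoglobin, immunoglobulin and sex-linked genes were left out. The text prints only part of the genes this rule takes, and that part was chosen after their values were seen. Results of some single genes are not reported here, though counts of genes and of list members include them. 5 sets against 5 fall apart without overlap in 0.794% of genes by chance.

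Shares of classes per hashtag set were compared with two-sided exact permutation tests, adjusted over the classes and contrasts of a gate. The smallest p for 5 sets against 5 is 0.00794. The bleomycin signature score of a set was the mean log2 CPM (prior count 2) of up to 100 genes raised by bleomycin minus that of up to 100 lowered, and no set was scored with a signature it helped to define. The spread between hashtag sets was checked against 1000 relabellings of the cells of each library.

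Alternatives fixed in advance were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a fit of only the contrast's treatments, a stricter hashtag rule (30 counts, 10 times), removal of only the cells with several tags, at least 50 cells per set, the hashtag number as a block, leaving out each set in turn, resolution 0.5 for shares, 50 signature genes and the estimated correlation. Alternatives added after the data were seen are named where their values are given. The main one of them tested the change of a class relative to the change of the other cells of named classes in the same hashtag sets (unnamed clusters left out). It removes what a whole library shares, and also any real change that all cells of a gate share. The mix of the other cells differed between treatments, and such differences enter its values. Other groupings of the sets were limited to 40 draws per comparison.

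The tests were tested on simulated data, with 200 genes changed in the anti-IL6R contrast. In fibroblasts (13310 genes) the edgeR step recovered 70.1%, 85.1% and 98.5% of genes changed 1.5, 2 and 4 times, with 7 false calls among 176. In interstitial macrophages (5880 genes) it recovered 23.9%, 40.3% and 83.3%. When 300 further genes of fibroblasts were shifted in the whole library, the edgeR step made 289 false calls (13324 genes) and the relative test 2, and the relative test recovered 19.4%, 43.3% and 74.2%. The simulated other cells had the same mix in all treatments, so false calls from a changed mix were not covered. Raw reads were not used here.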

Results

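Single-cell RNA sequencing was carried out on mouse lungs 24 days after intratracheal saline or bleomycin, a DNA-damaging drug that scars the lung, a time the series describes as the resolution of the injury. The 5 treatments were PBS, bleomycin with an isotype control antibody, bleomycin with an antibody against the interleukin 6 receptor (anti-IL6R), bleomycin with an antibody against oncostatin M (anti-OSM), and bleomycin with both antibodies. Interleukin 6 and oncostatin M are cytokines whose receptors share the signalling chain gp130. Each treatment was profiled in 3 sort gates: CD45+ cells, a gate written CD31/EpCAM, and cells negative for these 3 markers. The 15 gene expression libraries held between 6666 and 20386 barcodes, and between 40404470 and 81915291 UMIs. After filtering, 5385 to 13053 cells per library were analysed. Median UMIs per cell in the order PBS, isotype, anti-IL6R, anti-OSM and both were 2440, 2254, 3027, 2795 and 3024 in the CD45+ gate, 4218, 5025, 3006, 3263 and 5354 in the CD31/EpCAM gate, and 4926, 6148, 4379, 5959 and 4708 in the triple-negative gate. Every treatment of a gate was a single library, so a difference between treatments is also a difference between libraries.

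Each library held 5 sets of cells marked by hashtags, and these 75 sets were the replicates (n = 5 per treatment and gate unless stated). In all 15 libraries the cell classes were spread over the sets more unevenly than in any of 1000 random relabellings of the cells (permutation p = 0.001, the smallest they can give). Fibroblasts were present in 2 gates, and each of the 25 fibroblast sets of the triple-negative gate resembled the set with the same hashtag and treatment in the CD31/EpCAM gate more than the other 4 sets (median r = 0.294 across 5579 genes, against -0.0854 for other hashtags, with 5 matches given by chance; genes are not independent replicates). The fibroblast class held adventitial, alveolar, peribronchial and fibrotic clusters. An adventitial cluster led by Ifi205 was its largest part with PBS (16.4% of cells), isotype (17.7%) and both antibodies (15.5%), an adventitial cluster led by Sult1e1 with anti-IL6R (16.4%), and an alveolar cluster led by Npnt with anti-OSM (17.1%, against 6.13% with isotype). Among general capillary endothelial cells, 1 cluster led by Kit and Sema3c was largest with PBS (41.8%), isotype (37.6%) and anti-IL6R (51.7%), and 1 led by Kit and Hpgd with anti-OSM (38.4%) and both antibodies (33.2%). Alveolar type 2 cells and both macrophage classes were single clusters. Interstitial macrophages of PBS lungs reached 20 cells in only 2 sets.

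The makeup of the CD45+ gate at day 24 still differed between bleomycin and PBS. Alveolar macrophages made up 16.2% ± 4.93 (SD) of immune cells with PBS and 4.83% ± 2.42 with bleomycin and isotype, B cells fell from 23.3% ± 4.13 to 12.9% ± 1.97, interstitial macrophages rose from 1.48% ± 0.85 to 5.26% ± 0.70 and dendritic cells from 5.81% ± 1.89 to 16.3% ± 3.06, with no overlap between sets (exact p = 0.00794 each, adjusted p = 0.0231). Monocytes rose from 7.57% ± 1.42 to 10.8% ± 1.69 (exact p = 0.0159, adjusted p = 0.0363). With anti-IL6R the B cell share was 33.5% ± 4.02, above isotype, and dendritic cells (8.81% ± 1.09), monocytes (5.65% ± 1.78) and NK cells (9.73% ± 2.31, against 13.7% ± 1.06 with isotype) were below it (exact p = 0.00794 each, adjusted p = 0.0231). Interstitial macrophages also fell, to 3.47% ± 0.76 (exact p = 0.0159, adjusted p = 0.0363), a call lost when the unnamed macrophage cluster with high Mmp12 and Gpnmb was counted with them (4.72% against 6.44%, exact p = 0.0714, adjusted p = 0.114). With anti-OSM only the NK cell share changed, to 8.32% ± 0.81 (exact p = 0.00794, adjusted p = 0.0231). With both antibodies B cells rose to 22.2% ± 3.45 and monocytes fell to 6.95% ± 1.13 (exact p = 0.00794 each), and neutrophils rose from 5.85% ± 1.07 to 8.23% ± 1.54 (exact p = 0.0159). Of 32 comparisons 14 were called by the exact permutation test. T cell shares, between 23.1% and 29.8%, were in none of them. The calls at exact p = 0.0159 were each lost without any of 8 of their 10 sets (adjusted p between 0.0564 and 0.0726). Shares within a gate sum to 100%, so a rise of 1 class lowers the others, and the gate is set by the sort.

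**Figure D1:**
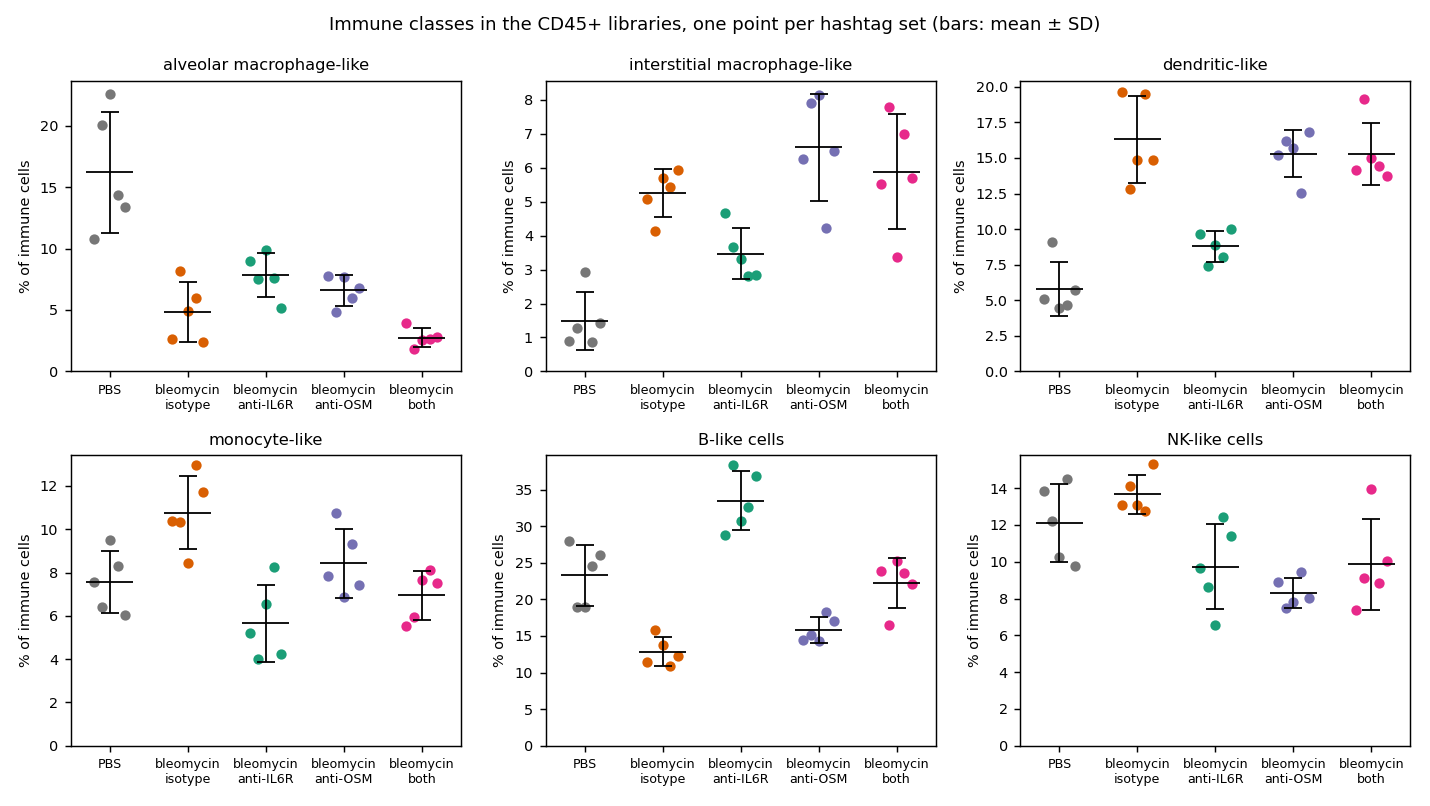
Share of CD45+ cells (percent of immune cells, vertical axis) of 6 immune classes in each hashtag set (points) with the mean and SD of 5 sets for the 5 treatments. Alveolar macrophages stood at a mean of 16.2% with PBS and 4.83% with bleomycin and isotype, and B cells at 12.9% with isotype and 33.5% with anti-IL6R.

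By the exact permutation test 0 class shares were called in the other gates (10 of 36 comparisons in the CD31/EpCAM gate and 4 of 20 in the triple-negative gate had an unadjusted p below 0.05, and no other tool was run). In the CD31/EpCAM gate alveolar type 2 cells were 82.4% of epithelial cells with PBS and 61.5% with isotype (exact p = 0.0238, adjusted p = 0.107). General capillary and lymphatic cells with anti-IL6R had exact p = 0.00794 (adjusted p = 0.0952, the gate's lowest). In the triple-negative gate fibroblasts were 89.8% of mesenchymal cells with isotype, 86.2% with anti-OSM and 92.7% with both antibodies, and smooth muscle cells 4.07%, 7.67% and 2.51% (lowest adjusted p of the gate 0.119). A fibrotic cluster led by Cthrc1 and Grem1 held 0.0755% of mesenchymal cells (unnamed clusters included) with PBS and 2.38% with isotype (exact p = 0.00794, adjusted p = 0.0476). It held 2.75% with anti-IL6R, 6.76% with anti-OSM (exact p = 0.0397) and 1.16% with both (exact p = 0.0476, adjusted p = 0.0952 each). Its defining genes differ between treatments, and its p-values were adjusted only with other single clusters.

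Some RNAs moved in every class with the library. The mitochondrial ribosomal RNA mt-Rnr1 was lower with isotype than PBS in all 5 classes (log2 fold changes -3.20 to -1.49). Against isotype it rose with anti-IL6R (1.25 to 2.06) and with both (1.20 to 2.35) and differed little with anti-OSM (-0.48 to 0.30). The long non-coding RNA AY036118 (chromosome 17:39847113-39848035) moved alike (-2.46 to -1.52, 1.46 to 1.98, -0.09 to 0.42 and 1.35 to 1.90). So did Fosb, an early gene induced by dissociation (-1.29 to -0.75, 0.38 to 0.82, 0.03 to 0.42 and 0.73 to 0.94). Fosb was not called in alveolar macrophages with anti-IL6R (adjusted p = 0.514) or interstitial ones with bleomycin (0.149). Median mitochondrial UMIs per cell (PBS, isotype, anti-IL6R, anti-OSM, both) were 4.16%, 1.71%, 3.15%, 1.38% and 3.34% in the CD31/EpCAM gate. They were 2.89%, 1.33%, 2.32%, 1.52% and 2.48% in the CD45+ gate. In the triple-negative gate they were closer, 2.06%, 1.57%, 2.14%, 1.71% and 1.85%. These movements accompany all gene groups described for the contrasts that part these libraries.

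The first comparison asked what bleomycin left in the lung at day 24. In fibroblasts 15 of 29 extracellular matrix genes rose and 1 fell, 7 of 15 genes of fibrotic fibroblasts rose and 6 of 12 genes of alveolar fibroblasts fell. Cthrc1 (chromosome 15:39076932-39087121, GRCm38), a collagen-regulating protein of scar fibroblasts, rose from 7.06 to 35.7 CPM (log2 fold change 2.37 ± 0.54 SE), Grem1, an inhibitor of BMP signalling, by 3.22 ± 0.88, the matrix protein tenascin C (Tnc) by 2.23 ± 0.50 and Ltbp2 by 1.58 ± 0.40. These 4 are among the leading genes of the fibrotic cluster, which held 0.0951% of the class with PBS and 3.05% with isotype. In adventitial fibroblasts alone Cthrc1 (0.19), Tnc (0.43) and Ltbp2 (0.37) were not called, and in alveolar fibroblasts alone Tnc was (1.48, adjusted p = 0.0357) and Ltbp2 was not (0.93). Sparc rose from 3324 to 5374 CPM (0.69 ± 0.19). Of the alveolar fibroblast genes Slc7a10 fell by 1.44 ± 0.31 and the transcription factor Tcf21 by 0.35 ± 0.09. MHC class II genes, which present antigen, rose in 5 of 6 cases (Cd74 2.32 ± 0.53, from 2.60 to 13.3 CPM), interferon-induced genes in 7 of 19 with 2 lower (Ifi44 2.19 ± 0.36). So did p53 targets in 6 of 15 cases, with 1 lower (Eda2r 0.63 ± 0.13, Fas -0.60 ± 0.09). Of 25 genes that respond to gp130 and STAT3, 12 fell and 2 rose. Among them the chemokine Ccl2 fell from 294 to 88.9 CPM (-1.72 ± 0.28) and Il6 itself from 561 to 298 CPM (-0.91 ± 0.20). Dissociation stress genes fell in 9 of 14 cases (Atf3 -0.81 ± 0.11). In all, 2571 of 13446 genes were called (1190 up, 1381 down). 19 matrix, 8 fibrotic, 5 MHC class II, 8 interferon, 7 p53 and 2 gp130 genes rose, and 1 matrix, 2 interferon, 1 p53, 13 gp130, 7 alveolar fibroblast and 9 stress genes fell, adjusted over the list alone. The list tests for matrix (adjusted p = 9.9e-07), stress (1.0e-06), MHC class II (0.00105), fibrotic (0.00144), gp130 (0.00341), alveolar fibroblast (0.00414), p53 (0.0187) and interferon genes (0.0283) gave adjusted p = 0.421, 0.135, 0.213, 0.471, 0.475, 0.482, 0.337 and 0.733 with an estimated correlation. In the change relative to the other cells of the same sets, 28 genes were called, 20 of them among the 2571. Nop58, a ribosomal RNA processing factor, was lower in both (-1.17 ± 0.16 and -1.27). Of the calls, 990 were also made in fibroblasts of the CD31/EpCAM gate in the same direction (329 by chance) and 108 in the opposite direction.

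Alveolar type 2 cells, which make surfactant and renew the alveolar epithelium, had higher p53 targets, genes of the DNA damage response, at day 24. Of 13 measured 8 rose, among them Phlda3 (chromosome 1:135766119-135769136), a repressor of AKT, from 4.71 to 41.7 CPM (3.07 ± 0.20, adjusted p = 3.7e-15), the nuclease Aen (1.65 ± 0.21), the cyclin Ccng1 (1.47 ± 0.16) and the death receptor Fas (1.42 ± 0.26). Acute-phase genes rose in 7 of 9 cases, with the iron-binding Lcn2 from 816 to 2336 CPM (1.51 ± 0.25) and the glycoprotein Lrg1 from 284 to 787 CPM (1.44 ± 0.24). MHC class II genes rose in 6 of 7 (Cd74 0.65 ± 0.05, H2-Aa 0.51 ± 0.05). Cholesterol synthesis genes fell in 6 of 17 cases (Insig1 -0.62 ± 0.15), and dissociation stress genes in 11 of 14 with 1 higher (Egr1 -1.15 ± 0.13). The paraoxonase Pon1 fell from 128 to 13.8 CPM (-2.94 ± 0.33). Matrix genes of fibroblasts rose in 8 of 15 cases and fell in 2, at low levels (Col3a1 18.2 against 6.37 CPM, Eln 12.3 against 4.43 CPM). Counts gave 3226 of 10287 genes (1676 up, 1550 down). The p53 call (adjusted p = 4.1e-10) held with an estimated correlation (adjusted p = 0.0152), and adjusted over the list alone 9 p53, 7 acute-phase, 6 MHC class II, 8 matrix genes and 1 stress gene rose and 2 matrix, 12 stress and 6 cholesterol genes fell. The acute-phase (0.00144), MHC class II (3.2e-06), matrix (0.00415), stress (2.5e-06) and cholesterol calls (0.00602) had adjusted p = 0.202, 0.121, 0.16, 0.16 and 0.692 with an estimated correlation. 1249 genes were called relative to the other cells of the sets, 898 of them in common, with Phlda3 at 2.56, Fas at 1.70 and Ccng1 at 1.09, while Lrg1 (-0.02) and Lcn2 (0.42) were not called.

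General capillary endothelial cells, the progenitors of the alveolar capillary bed, had higher Lrg1, a promoter of vessel growth, after bleomycin (65.0 to 287 CPM, 2.12 ± 0.30), and higher Tiam1 (1.34 ± 0.24) and Rgcc (1.27 ± 0.20), a cell cycle regulator. Matrix genes rose in 7 of 21 cases and fell in 1, led by Sparc (743 to 1627 CPM, 1.14 ± 0.12) and Col3a1 (1.15 ± 0.16). Transcripts of neighbouring cells fell: 8 of 13 surfactant and type 2 genes (Slc34a2 -0.90 ± 0.13, Sftpb -0.75 ± 0.09, Cxcl15 -0.79 ± 0.09) and 5 of 7 alveolar fibroblast genes (Inmt -1.32 ± 0.13, Npnt -0.75 ± 0.19), the named ones at low levels (Sftpb 49.0 against 81.9 CPM). 8 matrix genes rose and 2 fell, and 10 surfactant, 6 alveolar fibroblast and 8 stress genes fell, adjusted over the list alone. Dissociation stress genes fell in 5 cases (Hsp90aa1 -0.59 ± 0.14). The test called 1870 of 10441 genes (886 up, 984 down). The surfactant (adjusted p = 5.6e-12) and alveolar fibroblast calls (2.9e-05) held with an estimated correlation (adjusted p = 0.00615 and 0.0335), and the matrix (0.00992) and stress calls (0.00083) did not (adjusted p = 0.137 and 0.561 with an estimated correlation). 395 genes were called relative to the other cells, 179 of them in common, with Tiam1 at 1.37 and Rgcc at 1.62.

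The alveolar macrophage class, named after the resident phagocytes of the airspace, had higher genes of scar-associated macrophages. Of 14 measured genes of that list 10 rose and 2 fell, with osteopontin (Spp1, chromosome 5:104435118-104441050) from 644 to 4773 CPM (2.88 ± 0.40), the matrix-cleaving Mmp14 from 0.52 to 29.4 CPM (5.50 ± 0.55) and the lipid carrier Apoe from 88.8 to 549 CPM (2.60 ± 0.45). The complement gene C1qb (5.54 ± 0.82), Pou2f2 (3.72 ± 0.55), Lrg1 (3.71 to 51.9 CPM, 3.82 ± 0.37) and the haemoglobin scavenger Hp (3.48 ± 0.54) also rose. Identity genes of alveolar macrophages fell in 8 of 12 cases, with the scavenger receptor Marco from 354 to 46.0 CPM (-2.81 ± 0.50) and Ear1 by 1.53 ± 0.32, and cell cycle genes in 11 of 17 (Pclaf -2.50 ± 0.65, Cdk1 -1.98 ± 0.53; both calls lost when only cells with several hashtags were removed, that of Pclaf also with DESeq2). Cholesterol synthesis genes rose in 7 of 17 cases (Fdps 2.18 ± 0.47, Cyp51 1.06 ± 0.26), MHC class II genes in 4 of 6 (Cd74 1.09 ± 0.27), interferon genes in 2 of 9 (Ifi27l2a 2.47 ± 0.45), and Lrg1 and Ctss in the list of activated endothelium. Dissociation stress genes fell in 5 cases (Jun -1.29 ± 0.25). The test called 1593 of 8377 genes (868 up, 725 down). 11 scar-associated, 12 cholesterol, 5 MHC class II, 4 interferon, 2 acute-phase and 2 activated endothelial genes rose, and 2 scar-associated, 1 acute-phase, 15 cell cycle, 8 identity and 8 stress genes fell, adjusted over the list alone. Of the list tests, only that of acute-phase genes (Lrg1 and Hp of 3, adjusted p = 0.00414) held with an estimated correlation (adjusted p = 0.0495). The scar-associated (adjusted p = 5.6e-09), cell cycle (9.1e-06), cholesterol (1.5e-05), stress (2.7e-05), identity (0.000831), MHC class II (0.00419), activated endothelial (0.0219) and interferon calls (0.0271) had adjusted p = 0.0665, 0.358, 0.471, 0.297, 0.251, 0.392, 0.117 and 0.32 with an estimated correlation. 1147 genes were called relative to the other cells, 554 in common, with Mmp14, Spp1, C1qb, Lrg1, Pou2f2 and Pclaf among them and Marco (-0.42) and Apoe (1.13) not.

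In interstitial macrophages MHC class II genes rose in 5 of 7 cases (H2-Eb1 from 4972 to 11380 CPM, 1.20 ± 0.23, H2-Ab1 1.03 ± 0.24). The calls of these genes were lost without PBS set 3, when only these treatments were fitted and when unnamed clusters were added, that of H2-Ab1 also when only cells with several hashtags were removed. The list call (adjusted p = 2.2e-14) held with an estimated correlation (adjusted p = 0.0335). All 7 MHC class II genes and 4 scar-associated genes rose, adjusted over the list alone. Of the scar-associated list 3 of 13 rose over all genes (adjusted p = 0.00014, adjusted p = 0.0665 with an estimated correlation), and of 10 cholesterol synthesis genes 1 fell (3 adjusted over the list alone; adjusted p = 0.00132, adjusted p = 0.286 with an estimated correlation). With 2 sets in the PBS group, 189 of 6350 genes were called (117 up, 72 down), 125 without PBS set 1 and 117 without PBS set 3, where the lone set was assumed to vary like the others. The stricter hashtag rule gave 99 genes and adding unnamed clusters 295. 308 genes were called relative to the other cells, 56 in common, and the MHC class II genes were not among them (H2-Eb1 -0.31).

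The next comparison asked what blocking the interleukin 6 receptor changed in bleomycin-treated lungs. In fibroblasts MHC class II genes fell in 4 of 6 cases (4 adjusted over the list alone), at low levels (Cd74 from 13.3 to 3.19 CPM, -2.04 ± 0.53, H2-Eb1 -1.61 ± 0.35; adjusted p = 0.0168, adjusted p = 0.358 with an estimated correlation), thrombospondin 1 (Thbs1) rose from 654 to 1363 CPM (1.06 ± 0.27) and Socs3, a feedback inhibitor induced by gp130 signalling, fell from 662 to 525 CPM (-0.33 ± 0.08). Atp5l (-1.19 ± 0.04) and Ndufb4 (-1.14 ± 0.06), which encode mitochondrial proteins, fell, with changes of -0.53 each in fibroblasts of the CD31/EpCAM gate. Collagen 1 did not move (Col1a1 2801 against 2851 CPM, -0.03 ± 0.18). The test called 3431 of 13446 genes (1495 up, 1936 down), of which 1524 were called in the same direction in fibroblasts of the CD31/EpCAM gate (397 by chance) and 18 in the opposite direction. Relative to the other cells of the sets the edgeR test called 0 genes (1061 had an unadjusted p below 0.05, and no other tool was run). That test set them against 868 cells of other named classes with anti-IL6R and 902 with isotype.

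In alveolar type 2 cells 8 of 15 matrix genes rose with anti-IL6R at low levels (Fn1 from 4.45 to 11.8 CPM, 1.34 ± 0.24, Eln 0.98 ± 0.15). Matrix genes rose in this library's capillary cells too, and RNA of other cells was not excluded. Bcl2l11, which promotes apoptosis, rose (0.80 ± 0.17), as did 6 dissociation stress genes (Hspa1b 0.89 ± 0.23, Hsp90aa1 0.47 ± 0.10). Cd74 (-0.41 ± 0.05) and H2-Aa (-0.28 ± 0.05) fell. With an estimated correlation the matrix list call (adjusted p = 4.2e-05) held (0.0245). The stress (0.000273) and MHC class II calls (0.00598) did not (0.288 and 0.363). 8 matrix and 7 stress genes rose and 3 MHC class II genes fell, adjusted over the list alone. Of 10287 genes 1239 were called (540 up, 699 down; 677 with the stricter hashtag rule), and relative to the other cells 66, of them 41 in common.

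In general capillary endothelial cells every one of 13 surfactant and type 2 genes rose with anti-IL6R, among them Sftpc (chromosome 14:70520949-70524081) from 719 to 3015 CPM (2.07 ± 0.05), Sftpa1 (2.05 ± 0.07) and Sftpd (1.95 ± 0.17), as did the macrophage gene Lyz2 (2.09 ± 0.09). These are genes of other cell types, and this library stood apart in its gate with 20386 barcodes and 5155 cells of several hashtags (8891 to 14818 and 750 to 1460 in the others). Acute-phase type 2 genes rose in 5 of 6 cases (Lcn2 1.74 ± 0.19, Chil1 1.70 ± 0.18), matrix genes in 14 of 21 with 1 lower (Col6a3 1.41 ± 0.23), alveolar fibroblast genes in 4 of 7 (Ces1d 1.75 ± 0.23, Inmt 0.95 ± 0.13), transitional epithelial genes in 4 of 14 (Nupr1 1.35 ± 0.19) and gp130 genes in 7 of 19 (Mt1 0.93 ± 0.11). The first 4 of these lists, with adjusted p = 4.2e-100, 1.0e-06, 1.1e-09 and 1.3e-05, held with an estimated correlation (adjusted p = 7.9e-09, 0.00175, 0.000469 and 0.0245). The transitional (0.0297) and gp130 calls (0.000224) had adjusted p = 0.202 and 0.17 with an estimated correlation. 13 surfactant, 5 acute-phase, 15 matrix, 5 alveolar fibroblast, 4 transitional and 10 gp130 genes rose, and 1 matrix and 1 gp130 gene fell, adjusted over the list alone. In all 1932 of 10441 genes were called (962 up, 970 down). 64 genes were called relative to the other cells (62 up, 2 down), 60 of them in common, with Sftpc at 1.91, Ces1d at 1.77 and Lyz2 at 1.92.

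In alveolar macrophages Lrg1 (chromosome 17:56119678-56122001) was close to undetected with anti-IL6R, with 3 counts among 5488635 UMIs of the class against 136 among 2896375 with isotype, a ratio of 0.0116 (95% counting interval 0.00237 to 0.0348). Bcl3, a partner of NF-kB that STAT3 induces, fell from 18.8 to 6.35 CPM (-1.55 ± 0.33), Mcm6, a replication gene, by 1.20 ± 0.28, and S100a9, an abundant neutrophil gene, from 62.6 to 15.7 CPM (-1.97 ± 0.19). The mitochondrial Lars2 rose (0.95 ± 0.10). The acute-phase (2 of 3 down, adjusted p = 1.3e-06) and activated endothelial lists (1 down, Lrg1, adjusted p = 0.000232) held with an estimated correlation (adjusted p = 0.00163 and 0.0111). Cholesterol synthesis had 2 genes up (adjusted p = 1.3e-05, adjusted p = 0.471 with an estimated correlation). 2 acute-phase genes and 1 activated endothelial gene fell and 4 cholesterol genes rose, adjusted over the list alone. Of 8377 genes 295 were called (107 up, 188 down). 778 genes were called relative to the other cells, 46 in common, with Lrg1 and Bcl3 (-1.56) among them and S100a9 (-0.42) not. In interstitial macrophages 401 of 6350 genes were called (136 up, 265 down), among them Rpl39-ps (-1.60 ± 0.12), uncertain because of its copies. Zfp395 rose (1.11 ± 0.27). 132 genes were called relative to the other cells, 20 in common, and Zfp395 (0.70) was not.

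The comparison of anti-OSM with isotype asked the same of oncostatin M. In fibroblasts 6 of 12 alveolar fibroblast genes rose (9 adjusted over the list alone), with the integrin ligand nephronectin (Npnt, chromosome 3:132881745-132950291) from 177 to 457 CPM (1.37 ± 0.22), Cdo1 1.14 ± 0.21, the integrin Itga8 0.91 ± 0.19 and Limch1 0.78 ± 0.12. The adventitial Pi16 fell from 1059 to 631 CPM (-0.75 ± 0.13). These moved with the share of the alveolar clusters. In fibroblasts of the CD31/EpCAM gate none of Npnt (-0.04), Cdo1 (-0.05), Itga8 (-0.10) and Limch1 (-0.06) was called, while in alveolar fibroblasts alone all 4 were (0.94, 1.04, 0.57 and 0.41). The list call (adjusted p = 1.4e-08) had adjusted p = 0.131 with an estimated correlation. The TGF-beta list was called (adjusted p = 0.0165, adjusted p = 0.421 with an estimated correlation) with 0 called members (4 up adjusted over the list alone). The test called 861 of 13446 genes (443 up, 418 down), 42 of them in both gates in the same direction (7.61 by chance) and 19 in opposite directions. 14 genes were called relative to the other cells, 5 in common. Tested apart, adventitial fibroblasts gave 57 genes and alveolar fibroblasts 830, but the cluster led by Npnt held 30.6% of alveolar fibroblasts with isotype and 55.0% with anti-OSM, so the 830 contain this shift. At resolution 0.5 only the cluster led by Npnt (2807 cells) was named alveolar.

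In alveolar type 2 cells 4 of 9 acute-phase genes (5 adjusted over the list alone) were lower with anti-OSM, among them Lrg1, which fell from 787 to 324 CPM (-1.29 ± 0.24) and Il33, an alarmin (-0.57 ± 0.11; call lost when only these treatments were fitted), and the prostaglandin synthase Ptgs1 (-0.80 ± 0.11) and Itih4 (-1.09 ± 0.19) fell with them. The receptor Osmr (chromosome 15:6813577-6874969), itself induced by STAT3, fell from 44.1 to 28.1 CPM (-0.70 ± 0.11). Of 13 surfactant and type 2 genes 6 fell and 1 rose, with the lipid enzymes Scd1 from 9643 to 5639 CPM (-0.77 ± 0.12) and Fasn (-0.42 ± 0.05) and the phosphate carrier Slc34a2 (-0.34 ± 0.04). In the same cells 5 of 17 transitional genes rose (Hbegf 0.59 ± 0.16, a call lost without a filter on low counts, without isotype set 2, 3 or 5 and without anti-OSM set 2 or 3). Anxa1 (0.92 ± 0.18), Thbs1 (0.77 ± 0.14) and 7 dissociation stress genes also rose (Dnajb1 0.49 ± 0.10). List calls for surfactant (adjusted p = 2.7e-05), transitional (7.1e-05), acute-phase (0.00019) and stress genes (3.4e-08) had adjusted p = 0.0984, 0.33, 0.123 and 0.0922 with an estimated correlation, and cell cycle genes were called (0.0174, adjusted p = 0.615 with an estimated correlation) with 0 called members. 7 surfactant genes fell and 1 rose, and 7 transitional and 9 stress genes rose, adjusted over the list alone. In all 659 of 10287 genes were called (427 up, 232 down), 414 without isotype set 4 and 439 with the stricter hashtag rule. 879 genes were called relative to the other cells, 218 in common, with Lrg1 (-1.44), Scd1 (-0.63), Fasn (-0.35) and Thbs1 (1.47) among them.

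General capillary endothelial cells had 182 of 10441 genes called with anti-OSM (99 up, 83 down). Genes of other cells rose again, the club cell secretoglobin Scgb1a1 from 645 to 1876 CPM (1.54 ± 0.06) and 6 of 13 surfactant genes (Sftpc 0.79 ± 0.05; adjusted p = 2.2e-14 and 0.00191 with an estimated correlation), with 1 of 14 transitional genes (4 adjusted over the list alone, against 6 surfactant genes up and 1 down; adjusted p = 0.000688 and 0.0335 with an estimated correlation). Agtrap fell (-0.41 ± 0.09). 167 genes were called relative to the other cells, 11 in common, without Scgb1a1 (1.12) or Sftpc (0.45). In alveolar macrophages 14 of 8377 genes were called (9 up, 5 down), 8 with the stricter hashtag rule and 58 without a filter on low counts. Mir6236 rose (0.72 ± 0.14), and Rps28 (-0.47 ± 0.08) and Rpl38 (-0.42 ± 0.07), which encode ribosomal proteins, fell. Of 17 cholesterol synthesis genes 13 rose when adjusted over the list alone, 1 over all genes (list adjusted p = 4.3e-19, adjusted p = 0.0948 with an estimated correlation). 408 genes were called relative to the other cells, 7 in common. Interstitial macrophages had 38 of 6350 genes called (29 up, 9 down), among them the autophagy gene Gabarapl2 (0.75 ± 0.15; call lost when unnamed clusters were added), between 14 and 24 genes without isotype set 2, 3 or 4 or anti-OSM set 2, 3, 4 or 5, and 0 relative to the other cells by edgeR (328 with an unadjusted p below 0.05, no other tool run). Adding unnamed clusters left 5 genes, and the DESeq2 Wald test gave 85. Scar-associated genes (2 up, 2 adjusted over the list alone, adjusted p = 0.0182) and gp130 genes (1 up, 3 adjusted over the list alone, adjusted p = 0.00333) had adjusted p = 0.264 and 0.296 with an estimated correlation. The calls of Spp1, Cd63 and Cebpd were lost without any 1 of 7, 8 and 8 of the 10 sets.

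With both antibodies, 6 of 9 acute-phase genes fell in alveolar type 2 cells (6 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 9.9e-07 and 0.0348). Lrg1 fell from 787 to 224 CPM (-1.79 ± 0.25), Lcn2 from 2336 to 1164 CPM (adjusted p = 0.0066), the prostaglandin E synthase Ptges by 0.90 ± 0.19 and Hp by 0.79 ± 0.10. MHC class II genes fell in 4 cases (Cd74 -0.42 ± 0.05; adjusted p = 0.0052, adjusted p = 0.358 with an estimated correlation), and 10 dissociation stress genes (Fosb 0.90 ± 0.12; adjusted p = 4.3e-08, adjusted p = 0.0922 with an estimated correlation) and Bcl2l11 (1.05 ± 0.17) rose. 5 MHC class II genes fell and 11 stress genes rose, adjusted over the list alone. In all 2124 of 10287 genes were called (933 up, 1191 down), and 90 relative to the other cells, 61 in common, with Lrg1 (-1.42), Ptges (-1.15) and Bcl2l11 (0.63) among them and Lcn2 (-0.30) and Hp (0.08) not.

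In fibroblasts 9 of 25 gp130 genes rose with both antibodies (11 adjusted over the list alone), among them Il6 from 298 to 563 CPM (0.92 ± 0.20), Ccl2 from 88.9 to 207 CPM (1.21 ± 0.27) and the metallothionein Mt2 (0.86 ± 0.18), and the chaperone Hyou1 rose (1.30 ± 0.23). Rps15 (-0.87 ± 0.05) and Pink1 (-0.70 ± 0.06) fell. List calls for gp130 (adjusted p = 0.00044), scar-associated (0.0168; Tgfbi and Cd63 down) and MHC class II genes (0.02; H2-DMb1 down) had adjusted p = 0.363, 0.297 and 0.363 with an estimated correlation. 4 scar-associated and 5 MHC class II genes fell, adjusted over the list alone. The Ccl2 call was lost when unnamed fibroblast clusters were added. The test called 2149 of 13446 genes (1084 up, 1065 down), 925 of them in both gates in the same direction (204 by chance) and 37 in opposite directions, and edgeR called 0 relative to the other cells (645 with an unadjusted p below 0.05, no other tool run). In general capillary endothelial cells Npr3, a clearance receptor for natriuretic peptides, rose from 123 to 309 CPM (1.33 ± 0.25) and Egr3 by 1.34 ± 0.28, 5 of 19 gp130 genes rose (Osmr 0.73 ± 0.13, Stat3 0.40 ± 0.08), and Rgcc, higher after bleomycin, fell from 192 to 105 CPM (-0.86 ± 0.19). Surfactant genes rose in 5 cases (Sftpc 0.47 ± 0.05) and stress genes in 4 (Hsp90aa1 0.53 ± 0.14, not called without both-antibody set 4). These lists (adjusted p = 0.039, 0.000433 and 0.0301) had adjusted p = 0.482, 0.156 and 0.742 with an estimated correlation. 5 gp130, 7 surfactant and 4 stress genes rose, adjusted over the list alone. The count was 1945 of 10441 genes (1032 up, 913 down), and 8 relative to the other cells, 6 in common, with Rgcc (-1.41) and Egr3 (1.41) among them.

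In alveolar macrophages 6 of 14 scar-associated genes fell with both antibodies (8 adjusted over the list alone). Apoe fell from 549 to 96.4 CPM (-2.43 ± 0.55), a call lost when only cells with several hashtags were removed, and Wfdc17 from 423 to 72.1 CPM (-2.51 ± 0.36). Spp1 stood at 1667 against 4773 CPM (-1.51 ± 0.39, adjusted p = 0.0286), a call lost when only these treatments were fitted, with the stricter hashtag rule and without isotype or both-antibody set 1, 3 or 5. Lrg1 was at 4 counts against 136 (a ratio of 0.0499, 95% counting interval 0.0134 to 0.131). The identity gene Chil3 rose (0.53 ± 0.10). The list tests for scar-associated (adjusted p = 6.4e-07) and identity genes (0.000865) had adjusted p = 0.123 and 0.251 with an estimated correlation, and the acute-phase (2 down, adjusted p = 7.6e-05) and activated endothelial lists (2 down, adjusted p = 0.00126) held (adjusted p = 0.0107 and 0.0245 with an estimated correlation). 2 genes of each of these fell and 3 identity genes rose, adjusted over the list alone. The test called 409 of 8377 genes (142 up, 267 down), 264, 233, 237 and 225 without isotype set 1, isotype set 5, both-antibody set 1 and both-antibody set 5, 163 when only these treatments were fitted, and 27 relative to the other cells, 16 in common, with Lrg1 and Wfdc17 (-2.38) among them. In interstitial macrophages 237 of 6350 genes were called (135 up, 102 down), and 470 with unnamed clusters added. The C-type lectin Cd209f fell from 157 to 9.80 CPM (-4.16 ± 0.69), as did Folr2 (-1.19 ± 0.24; call lost when unnamed clusters were added), both of the perivascular kind of these cells, and the SMAD inhibitor Skil rose (0.78 ± 0.11). Stress genes rose in 4 cases (Dusp1 0.46 ± 0.10; adjusted p = 0.00062), 1 TGF-beta gene rose (0.0246) and 0 interferon genes were called (0.0127), with adjusted p = 0.272, 0.124 and 0.582 with an estimated correlation (4 and 1 up and 1 down adjusted over the list alone). 9 genes were called relative to the other cells, 3 in common, with Cd209f (-4.26) among them.

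The interaction asked if both antibodies differed from the sum of each alone on the log2 scale. It was called for 868 genes in fibroblasts (513 up, 355 down), 542 in type 2 cells (157 up, 385 down) and 276 in capillary cells (102 up, 174 down). Alveolar macrophages had 83 (34 up, 49 down) and interstitial macrophages 22 (19 up, 3 down, 38 with unnamed clusters added). The interaction uses 4 libraries, and its terms included transcripts of other cell types. In capillary cells 9 of 13 surfactant genes were lower (11 adjusted over the list alone), with Sftpc at -2.39 ± 0.07. Their list had adjusted p = 2.3e-115 (6.0e-09 with an estimated correlation). RNA of other cells was not excluded in type 2 cells, matrix genes included. In alveolar type 2 cells Ifitm3 (-1.73 ± 0.28), an interferon-induced membrane protein, Ly6a (-1.62 ± 0.29), the p53 target Bax (-0.74 ± 0.13) and 4 matrix genes (8 adjusted over the list alone, with 1 above; Eln -1.37 ± 0.23, Col1a1 -1.32 ± 0.31; adjusted p = 0.000109 and 0.0245 with an estimated correlation) lay below the sum. In alveolar macrophages Rnf128, an E3 ligase, did so (-2.70 ± 0.43). Relative to the other cells 16, 582, 93, 194 and 108 genes were called in the 5 classes, 3, 123, 29, 24 and 1 of them in common, with Ifitm3 (-1.66), Ly6a (-1.24), Eln (-1.61), Col1a1 (-1.93) and Rnf128 (-3.23) among them. The type 2 count was 352 without isotype set 4. That of alveolar macrophages was 54, 53, 49 and 141 without isotype set 2, anti-IL6R set 3, anti-OSM set 5 and both-antibody set 4. It was 233 without a low-count filter and 146 by DESeq2.

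Among the targets and their signalling partners, Il6 (chromosome 5:30013114-30019981) had its highest level of the 5 classes in fibroblasts, at 561 CPM with PBS, 298 with isotype, 404 with anti-IL6R (0.44 ± 0.20, adjusted p = 0.119), 254 with anti-OSM (-0.23 ± 0.20, adjusted p = 0.59) and 563 with both. Osm (chromosome 11:4236420-4241026) passed the filter on low counts only in the macrophage classes of the 5 tested, at 166 CPM in alveolar and 79.8 CPM in interstitial macrophages with isotype, and was called in no contrast (in alveolar macrophages 0.70 ± 0.33 with bleomycin, adjusted p = 0.153). Il6ra (chromosome 3:89864059-89913196) stood at 131 and 166 CPM in these classes with no call. Il6st (chromosome 13:112464070-112510086), which encodes gp130, rose in capillary cells with anti-IL6R (0.31 ± 0.07) and both antibodies (0.29 ± 0.07) after a fall with bleomycin (-0.30 ± 0.07). Osmr in fibroblasts fell with bleomycin (-0.24 ± 0.05) and rose with anti-IL6R (0.30 ± 0.05), both antibodies (0.50 ± 0.05) and anti-OSM (0.20 ± 0.05), the last not without isotype set 3 or 4 nor in the CD31/EpCAM gate (-0.19). Col1a1 (chromosome 11:94936224-94953042) in fibroblasts was at 1996 CPM with PBS and 2851 with isotype (0.51 ± 0.18, adjusted p = 0.0453), a call lost without a filter on low counts, with the stricter hashtag rule, with unnamed clusters added, without PBS set 1, 2, 4 or 5 and without isotype set 1, 3 or 5. With anti-IL6R, anti-OSM and both it was at 2801, 2852 and 2598 CPM (adjusted p = 0.934, 1 and 0.663). Apart from the fall in fibroblasts with anti-IL6R, Socs3 (chromosome 11:117966079-117970047) was called in no class and contrast.

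**Figure D2:**
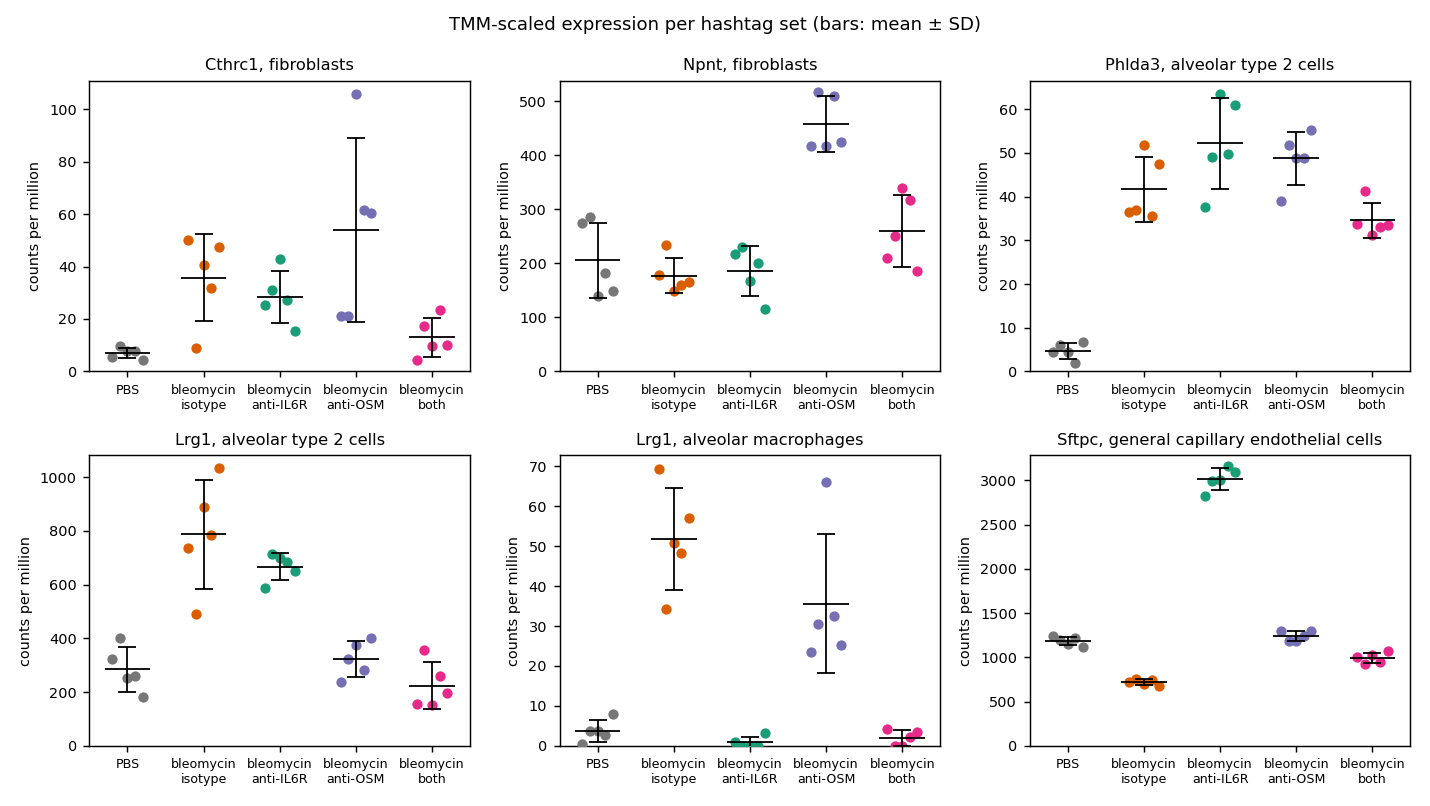
Level in CPM (linear vertical axis from 0) of 6 genes in each hashtag set (points) with the mean and SD of the sets for the 5 treatments: Cthrc1 and Npnt in fibroblasts, Phlda3 and Lrg1 in alveolar type 2 cells, Lrg1 in alveolar macrophages and Sftpc in general capillary endothelial cells. Phlda3 had a mean of 4.71 CPM with PBS and 41.7 CPM with isotype, and Sftpc in capillary cells 719 CPM with isotype and 3015 CPM with anti-IL6R.

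How far a class lay from isotype towards PBS along the genes called with bleomycin was measured by a cross-fitted score. In general capillary endothelial cells the score was 0.23 with PBS and 1.48 with isotype, and lower with anti-IL6R (0.69, difference -0.79, exact p = 0.00794, adjusted p = 0.0318) and both antibodies (0.57, difference -0.91, exact p = 0.00794, adjusted p = 0.0318), but not with anti-OSM (1.54, difference 0.06, exact p = 0.492). In alveolar type 2 cells it was 0.70 with PBS, 2.46 with isotype and 1.52 with both antibodies (difference -0.94, exact p = 0.00794, adjusted p = 0.0318), and 1.93 with anti-IL6R (exact p = 0.0238, adjusted p = 0.0571). Differences of -0.67 and -1.21 in alveolar macrophages with anti-IL6R and both antibodies and of -0.33 and -0.41 in fibroblasts were not called (lowest exact p = 0.0238, adjusted p = 0.0571). The score of the other cells in the capillary sets moved alike, from 1.42 with isotype to 0.85 with anti-IL6R and 0.73 with both, and with it subtracted no difference was called (lowest adjusted p = 0.267). Each of these 3 calls was lost without isotype set 1, 3, 4 or 5 (0 calls) or without any set of its own arm, where 4 sets against 5 allow no exact p below 0.0159. That for anti-IL6R in capillary cells was also lost without any set of both antibodies (0 calls), and that in type 2 cells with the stricter hashtag rule. Without isotype set 2 there were 8 calls. The isotype sets define the signature and are its reference, so a return towards PBS also contains what is particular to the isotype library. No score was computed for interstitial macrophages.

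**Figure D3:**
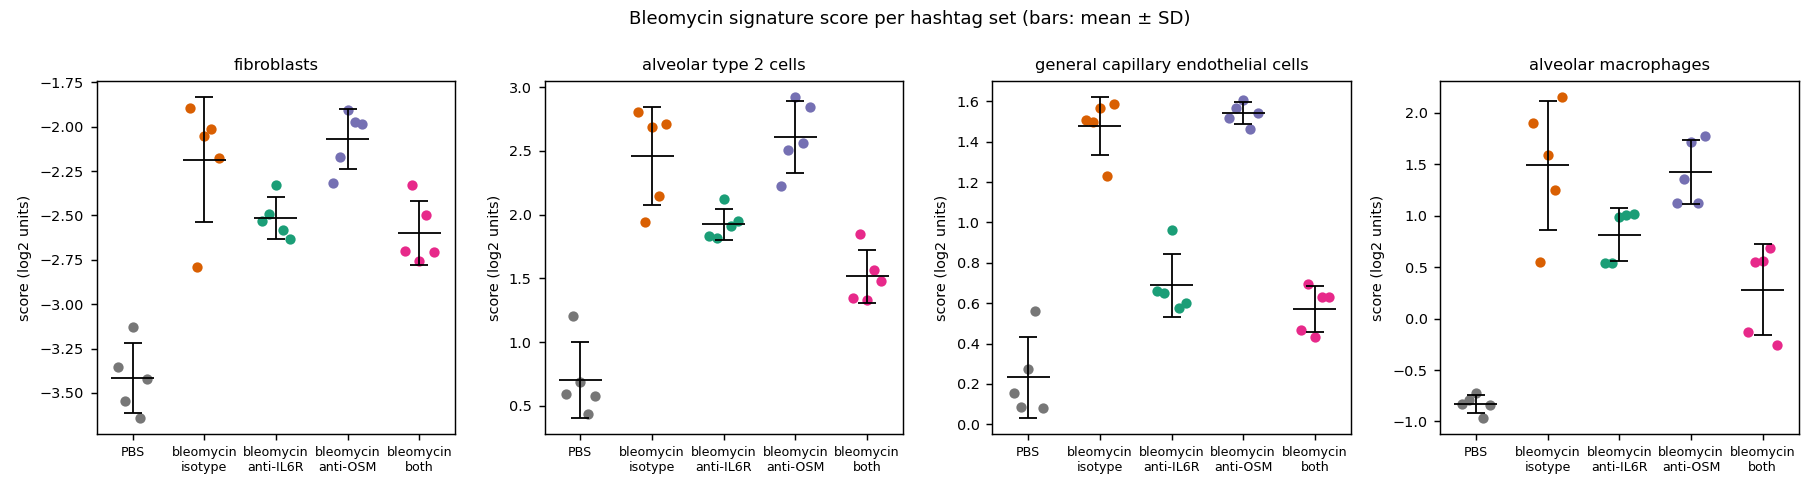
Bleomycin signature score (log2 units, vertical axis) of each hashtag set (points) with the mean and SD of the sets of 5 treatments in 4 classes. In general capillary endothelial cells the mean was 1.48 with isotype, 1.54 with anti-OSM, 0.69 with anti-IL6R and 0.57 with both antibodies.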

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

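The tests that weigh explanations, the comparison of Lrg1 between classes and the other groupings of the hashtag sets were chosen after the results were seen. Sets that stood apart from their group were sought in 605 groups, and 38 were found, where chance gives about 1 in 20 groups. The value given for each is the gap of the highest or lowest set to its nearest neighbour, divided by the range of the 5 sets.

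In fibroblasts 1 PBS set stood apart for Tnc (0.783), Grem1 (0.727), H2-Aa (0.857) and Socs3 (0.749), and 1 anti-OSM set for Scgb1a1 (0.917), a gene of club cells. In alveolar type 2 cells this held for Orm1 (0.762) and Pon1 (0.714) with PBS, Il6 (0.819) and Rpl39-ps (0.729, uncertain for its copies) with isotype, Krt8 (0.796) with anti-OSM, and Lcn2 (0.736), Fosb (0.711) and Osmr (0.84) with both antibodies. In general capillary endothelial cells it held for Cyp1a1 with PBS (0.952) and isotype (0.776), for Trim37 (0.841), Scgb1a1 (0.738), Chil1 (0.721) and Lcn2 (0.733) with isotype, for Lcn2 with anti-IL6R (0.865) and for Lyz2 with anti-OSM (0.825). In alveolar macrophages it held for Jun with PBS (0.825), Mmp12 (0.851) and Chil3 (0.832) with isotype, Lrg1 with anti-IL6R (0.726, on 3 counts) and Hp with both antibodies (0.866). In interstitial macrophages it held for Tnip3 with both antibodies (0.732). Among shares of the CD45+ gate 1 set stood apart for interstitial macrophages (0.723) and dendritic cells (0.722) with PBS and for dendritic cells with both antibodies (0.767). In the CD31/EpCAM gate this concerned type 2 cells with both antibodies (0.761) and type 1 cells with isotype (0.813) and both (0.75). In the triple-negative gate it concerned mesothelial cells with PBS (0.96) and isotype (0.814) and the unnamed fibroblast clusters with both antibodies (0.748). The signature score of capillary cells had such a set with isotype (0.756) and with anti-IL6R (0.777).

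Several genes moved in opposite directions in 2 classes with no overlap of sets, and these differences were not tested. With bleomycin Fas was higher in type 2 cells and lower in fibroblasts (difference 2.02 log2 units), Npnt higher in type 2 and lower in capillary cells (1.52), and Rgcc higher in capillary cells and lower in fibroblasts (2.14). Nme2 was higher in fibroblasts and lower in type 2 (2.49) and capillary cells (2.92). With anti-IL6R, capillary cells were higher and type 2 cells lower for the type 2 genes Sftpc (2.40), Sftpd (2.27), Sftpa1 (2.24) and Chil1 (2.08) and for Lyz2 (2.40). Mt1 was higher in capillary cells and lower in interstitial macrophages (1.62). Thbs1 was lower in interstitial macrophages and higher in fibroblasts (difference 2.98), type 2 cells (2.57) and capillary cells (3.14). With anti-OSM Anxa1 was lower in fibroblasts and higher in type 2 cells (1.04) and alveolar macrophages (0.44), Fhod1 was higher in fibroblasts and lower in interstitial macrophages (1.78), and Osmr higher in fibroblasts and lower in type 2 cells (0.91). The call of Fhod1 in interstitial macrophages was lost without isotype set 1, 2 or 4 or anti-OSM set 2 or 3, and that of Osmr in fibroblasts without isotype set 3 or 4. With both antibodies Sftpc was higher in capillary and lower in type 2 cells (0.73).

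A cluster with high Mmp12 and Gpnmb, left without a name, held 1.25% ± 0.48 (SD, 117 cells) of immune cells with isotype and 0 cells with PBS (exact p = 0.00794, adjusted p = 0.0476). It held 1.30% with anti-IL6R, 1.23% with anti-OSM and 0.678% with both antibodies (exact p = 0.0476, adjusted p = 0.0952, against isotype).

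Lrg1 in alveolar macrophages was lower with anti-IL6R, and the change differed from that in type 2 cells by -4.89 log2 units (exact permutation p = 0.00794 over hashtag-paired differences, adjusted p = 0.0119), with anti-OSM by 0.66 (exact p = 0.0397) and with both antibodies by -2.58 (exact p = 0.00794). Free RNA as the cause was argued against, since the levels of S100a8 and Sftpc in isotype macrophages predicted 1.28 CPM of Lrg1 from neutrophils and 0.0283 CPM from type 2 cells, against 47.0 CPM measured. A shift of the whole library was also argued against, because Lrg1 fell relative to the other cells of the same sets (-6.06, adjusted p = 5.2e-05 by edgeR). So was a loss of the cells added by bleomycin as a whole, since 200 genes raised more than 2-fold by it had a median change of -0.0841 (quartiles -0.46 to 0.22). A median over many genes cannot tell whether a small part of the cells, rich in Lrg1, was lost. With 3 counts the fitted changes depend on the prior count. An effect of blocking IL6R in these cells may account for the difference between classes, but it rests on 1 library per treatment and cannot be told apart from another difference between the libraries.

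Mitochondrial ribosomal RNA was lower with isotype and anti-OSM than with the other treatments. Sequencing depth was argued against, because these libraries lay on 1 side of the others in median UMIs in only 1 of 3 gates. A batch of library preparation stayed open, since mt-Rnr1 moved by at least 1 log2 unit in the same direction in 15 of 15 comparisons of 5 classes and 3 contrasts, which an effect of the treatments would give as well, and the labels give no such batch. Damage rich in mitochondrial RNA stayed open, as mitochondrial messenger RNAs had a median change of 0.56 (quartiles 0.24 to 0.95, 124 values) with anti-IL6R and both antibodies against 1.33 for the ribosomal RNAs. An effect of the antibody on the animals stayed open too, with changes in fibroblasts that differed by 0.39 between gates with anti-IL6R and stood at 0.27 and -0.69 with anti-OSM.

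For 24 counts of genes, 40 groupings of the hashtag sets compared, the real one included, were tested with only the treatments compared. In each case only 1 of 40, the real one, gave as many genes, the lowest share possible, unadjusted over the 24 counts. The other groupings mix libraries, so the real one can lead wherever libraries differ, whatever the cause. In fibroblasts the real grouping gave 2412, 3255, 733, 1901 and 773 genes for bleomycin, anti-IL6R, anti-OSM, both antibodies and the interaction, and the highest other 4, 0, 94, 1 and 1. In type 2 cells the real counts were 3140, 1261, 491, 1880 and 455 and the highest others 0, 14, 4, 3 and 20. Capillary cells had 1725, 2018, 207, 1859 and 283 against 1, 9, 15, 1 and 0, and alveolar macrophages 1652, 284, 23, 163 and 63 against 0, 17, 4, 54 and 1. Interstitial macrophages had 373, 63, 289 and 26 against 8, 3, 2 and 13 for anti-IL6R, anti-OSM, both and the interaction, and no such test was run for bleomycin with its 2 PBS sets.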

How the results depend on the processing

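The change relative to the other cells, the fibroblast classes taken apart, the overlap between gates, the unnamed clusters and the subtraction of other cells from the signature were chosen after the data were seen; the other alternatives were planned. DESeq2 size factors, the block and resolution 0.5 left every count within 1.5 times its value. The change relative to the other cells moved counts most. In the order bleomycin, anti-IL6R, anti-OSM, both antibodies and interaction it gave 28, 0, 14, 0 and 16 genes in fibroblasts (2571, 3431, 861, 2149 and 868 for the class alone) and 308, 132, 0, 9 and 108 in interstitial macrophages (189, 401, 38, 237 and 22). In alveolar type 2 cells it gave 1249 genes with bleomycin, 66 with anti-IL6R and 90 with both antibodies (3226, 1239 and 2124 alone). In capillary cells it gave 395, 64 and 8 for the same contrasts and 93 for the interaction (1870, 1932, 1945 and 276 alone). In alveolar macrophages it gave 778 genes with anti-IL6R, 408 with anti-OSM, 27 with both and 194 for the interaction (295, 14, 409 and 83 alone). Part of this follows from its construction, since it removes what all cells of a gate share and recovered fewer simulated changes. In fibroblasts 990, 1524, 42, 925 and 68 genes were called in the same direction in the CD31/EpCAM gate too, and 108, 18, 19, 37 and 45 in the opposite direction. Adventitial fibroblasts alone gave 1462, 1604, 57, 1089 and 247, and alveolar fibroblasts alone 1307, 1270, 830, 891 and 496, from fewer cells. The stricter hashtag rule gave 677 genes with anti-IL6R and 439 with anti-OSM in type 2 cells, 8 with anti-OSM in alveolar macrophages and 99 with bleomycin in interstitial macrophages. Without a filter on low counts the anti-OSM counts were 58 in alveolar and 61 in interstitial macrophages, by the DESeq2 Wald test 52 and 85, with only the treatments compared 23 and 63, with only cells of several hashtags removed 24 and 21, and with at least 50 cells per set 40 and 62. The interaction in alveolar macrophages was 233 without the filter and 146 by DESeq2, and both antibodies gave 163 with only these treatments. Adding the unnamed cluster to interstitial macrophages gave 295 genes with bleomycin, 5 with anti-OSM, 470 with both and 38 for the interaction. At least 50 cells per set could not be asked for both antibodies and the interaction in alveolar macrophages, or for bleomycin, anti-IL6R and the interaction in interstitial macrophages, where too few sets were left. Of 380 list tests 108 were called, 22 with an estimated correlation, and 58 of the 108 were called in the same direction relative to the other cells (117 called there, 24 with an estimated correlation). The signature gave 3 calls, 5 with 50 genes and 0 after subtraction of the other cells. The cause of these shifts was not tested beyond what is said here.

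Leaving out each set in turn gave 2113 to 2411, 2796 to 3214, 605 to 1082, 1743 to 1984 and 623 to 1065 genes in fibroblasts, in the order of contrasts above. In type 2 cells it gave 2796 to 3196, 863 to 1202, 414 to 661, 1740 to 2109 and 352 to 636, with the lowest anti-OSM and interaction counts without isotype set 4. Capillary cells gave 1531 to 1748, 1627 to 1812, 124 to 157, 1654 to 1800 and 233 to 280. Alveolar macrophages gave 1238 to 1679, 218 to 300, 11 to 20, 225 to 522 and 49 to 141. With both antibodies the counts there without isotype set 1 or 5 or both-antibody set 1 or 5 were 264, 233, 237 and 225. For the interaction they were 54, 53, 49 and 141 without the sets named with its results. Interstitial macrophages gave 117 to 200, 302 to 418, 14 to 51, 165 to 270 and 19 to 24, with 125 and 117 genes for bleomycin without PBS set 1 or 3. Their anti-OSM count was 14, 21 and 16 without isotype set 2, 3 or 4, and 21, 24, 21 and 23 without anti-OSM set 2, 3, 4 or 5. Called shares were 11 to 16 in the CD45+ gate and 0 to 0 in the others. Signature calls were 0 to 8, with 8 without isotype set 2 and 0 without isotype set 1, 3, 4 or 5 or any both-antibody set.

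With the hashtag number as a block the counts were 2604, 3522, 938, 2221 and 984 in fibroblasts, 3140, 1173, 682, 2092 and 552 in type 2 cells, 1847, 1954, 187, 1931 and 266 in capillary cells, 1564, 283, 13, 367 and 86 in alveolar macrophages, and 142, 378, 30, 214 and 22 in interstitial macrophages. Sets of different treatments share only this number. Their deviations correlated with a median between 0.00871 and 0.0657 over the 5 classes, pairs ranged from -0.300 to 0.430, and the best match had the same number in 7 of 20, 4 of 20, 5 of 20, 4 of 20 and 7 of 17 pairs, where chance gives 4 of 20 and 3.4 of 17. The naming rule and the fixed genes gave 296 values, of which the text prints part. Of 281 called, 226 stayed called in the same direction in every planned setting that left out no set, 55 were lost in at least 1 of them, 59 without at least 1 set, and 0 were reversed. Calls lost were 25 with the stricter hashtag rule, 20 with only the treatments compared, 20 with only cells of several hashtags removed, 16 without a filter, 11 with the block, 3 with DESeq2 size factors, 2 with the DESeq2 Wald test and 2 with at least 50 cells per set. Adding unnamed clusters, chosen later, ended 23. With anti-IL6R, 70.1%, 65.7%, 59.7%, 37.3% and 23.9% of simulated changes of 1.5 times were recovered in the 5 classes in the order above, and depth was not separated from cell number and spread as the limit.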

Other observations

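All tests in this part were chosen after the results of the 5 classes were seen, and the genes given were chosen after their values were seen. T cells of the CD45+ gate pooled 4 clusters whose mix differed between treatments. Clusters led by Dapl1 and Lef1, Cd8b1 and Cd8a, Tnfrsf4 and Ctla4, and Cd163l1 and Trdc held 64.2%, 18.0%, 6.54% and 11.3% of them with PBS and 34.5%, 27.4%, 23.0% and 15.1% with isotype. The first held 44.2%, 47.2% and 36.9% with anti-IL6R, anti-OSM and both. The changes given here are of this mix, and none was tested within a cluster. In the pooled T cells bleomycin raised Klrg1, a receptor of effector cells, to 54.2 CPM (log2 fold change 2.27 ± 0.34 SE, adjusted p = 2.7e-05). Areg, a tissue repair factor (2.16 ± 0.42), Il1rl1, the receptor of interleukin 33 (1.72 ± 0.50), and the inhibitory receptor Pdcd1 (1.60 ± 0.33) also rose, while Dusp10 fell (-1.65 ± 0.19). With anti-IL6R Klrg1 fell (-1.62 ± 0.30) and Nr4a3, a gene of recent receptor signalling, rose (1.09 ± 0.17), while Areg was not called (-0.54 ± 0.32, adjusted p = 0.234). With anti-OSM Il18rap (-1.31 ± 0.22) and Il2ra (-0.86 ± 0.25) fell, Klrg1 was not called (-0.74, adjusted p = 0.051), and the club cell gene Scgb1a1 rose from 21.0 to 1344 CPM (5.93 ± 1.28). With both antibodies Ell2 rose (1.65 ± 0.21) and Klrg1 was not called (-0.56, adjusted p = 0.213). In the order bleomycin, anti-IL6R, anti-OSM, both and interaction 2004, 2327, 1925, 912 and 247 of 8614 genes were called.

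In aerocytes, the capillary cells specialised for gas exchange (CD31/EpCAM gate), bleomycin raised Ntrk2, a neurotrophin receptor (2.91 ± 0.76, adjusted p = 0.0262), the matrix proteins Sparcl1 (2.44 ± 0.51) and Sparc (204 to 652 CPM, 1.67 ± 0.28), Rgcc (1.99 ± 0.48) and the thrombin receptor F2r (1.66 ± 0.32), and lowered Npr3 from 70.9 to 26.7 CPM (-1.49 ± 0.23) and Cyp1a1, induced by the aryl hydrocarbon receptor, from 342 to 9.87 CPM (-4.97 ± 1.18). The class pooled 2 clusters, and the smaller, led by Ednrb and richer in called doublets (12.8% against 0.269%, left out of the tests), held 22.4%, 19.8%, 20.8%, 11.8% and 14.5% of it with PBS, isotype, anti-IL6R, anti-OSM and both. With anti-OSM the endothelial genes Plvap (-1.19 ± 0.25), Cd93 (-1.27 ± 0.23) and Ptprb (-1.15 ± 0.22) fell. With both antibodies Npr3 rose (1.15 ± 0.23), while Rgcc (-0.66, adjusted p = 0.31) and Ntrk2 (-0.39, adjusted p = 0.698) were not called. The counts were 347, 464, 201, 509 and 76 of 7112 genes.

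Both antibodies against anti-IL6R also differ by the block of oncostatin M and share no library with anti-OSM against isotype. In type 2 cells Lrg1 (-1.56 ± 0.24, adjusted p = 0.000507), Itih4 (-0.89 ± 0.19), Ptges (-0.85 ± 0.19), Ptgs1 (-0.59 ± 0.11), Hp (-0.39 ± 0.10), Osmr (-0.37 ± 0.11) and Fasn (-0.29 ± 0.05) were lower there as well, while Lcn2 (-0.72, adjusted p = 0.0973), Scd1 (-0.38, adjusted p = 0.0626) and Il33 (-0.22, adjusted p = 0.291) were not called. Of 659 anti-OSM calls in type 2 cells 53.7% had the same sign there. Of genes called in both comparisons, 80 moved alike (20.7 by chance) and 56 oppositely (chance not computed). Fibroblasts had 42 and 127 (39.2), capillary cells 26 and 39 (6.54), alveolar macrophages 0 and 2 (0.119) and interstitial macrophages 9 and 0 (0.315).

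Besides type 2 cells, capillary cells and alveolar macrophages, Lrg1 rose with bleomycin in aerocytes (1.26 ± 0.31) and fibroblasts (2.55 ± 0.64, at 1.94 against 0.318 CPM), and no antibody contrast was called in aerocytes, capillary cells or these fibroblasts. In fibroblasts of the CD31/EpCAM gate it was not called with bleomycin (0.55 ± 0.38, adjusted p = 0.299) and rose with anti-IL6R (3.52 to 9.32 CPM, 1.42 ± 0.29). Unnamed fibroblast clusters, left out of the class by a threshold set after the data were seen, held 10.7%, 9.40%, 21.0%, 7.47% and 3.57% of mesenchymal cells of the triple-negative gate with PBS, isotype, anti-IL6R, anti-OSM and both (anti-IL6R exact p = 0.0317, adjusted p = 0.0952).

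Clock genes of 1 phase (Nr1d1, Nr1d2, Dbp, Tef, Hlf, Per2 and Per3) were higher with anti-IL6R, with median changes of 0.70 in fibroblasts (7 genes measured, 3 called), 0.93 in those of the CD31/EpCAM gate (7, 4 called), 0.74 in type 2 cells (6, 2 called), 1.08 in capillary cells (4, 3 called) and 0.36 in T cells (5, 1 called). With both antibodies the medians were 0.68, 0.91, 0.88, 0.73 and 0.01, with 3, 5, 3, 1 and 0 genes called. The library grouping seen in mitochondrial ribosomal RNA stayed open, since their median change from PBS to isotype was -0.16 over 29 values (quartiles -0.38 to -0.00186) against 0.79 with anti-IL6R, but -0.39 in fibroblasts of the CD31/EpCAM gate, with 0 of 7 genes above 0. A different hour of collection may also be a cause, but genes of the opposite phase (Arntl, Npas2 and Nfil3) had a median of -0.10 over 13 values. The labels give no hour, so this stayed open too, as did an effect of the antibody, which was not tested.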
